A study of Saccharomyces cerevisiae with 38 samples.

How the data were processed

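Yeast with the wild-type DED1 gene and yeast with the temperature-sensitive allele ded1-95 were grown in YPD and sampled at 30 °C or after 5 min at 37 °C. The 38 samples cover ribosome footprints, footprints after run-off, footprints from monosomes, mRNA, Ded1p binding sites by iCLIP and DMS probing of RNA structure. Groups and replicate numbers were taken from the sample labels alone. Per the labels, cultures were taken at an OD600 of 0.4 for footprints and mRNA, 1.0 for iCLIP and 0.6 for DMS. Cycloheximide was used at 56 µg/ml and DMS at 5%. The run-off labels carry the same cycloheximide text as the other footprint samples, so the run-off step itself is not given in the sources used here.

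The authors deposited 20 files of positions in which each value is a fraction, the share of a gene's signal that falls on that nucleotide. The values of a gene sum to 1 within 0.001 for 100% of genes in each of these files except the first iCLIP library, where this holds for 55% of genes. Positions without signal are not listed and no read totals are given. Depth is therefore known only as the number of listed positions, and no counting interval can be given for any share. A share carries no level between genes. For this reason the planned tests of footprints per ORF and of translational efficiency were not run, and the planned units scaled to library size were replaced by shares. The base given at each position matched the R64 (sacCer3) reference at 100% of positions, so that build was used for coordinates.

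For mRNA the authors deposited FPKM values of 7132 entries in each of 12 libraries. Of these entries, 416 had no gene identifier, and 6007 were coding genes. The FPKM of all entries summed to between 5.8e+06 and 2.13e+07 per library, and 73.4% to 99.6% of that sum lay in non-coding entries. The submitters' notes name CASAVA, Bowtie and TopHat without versions. Other steps before the deposited values are not given in the sources used here.

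Leaders were defined as the 100 nt upstream of the annotated start codon without the nearest 15 nt, and positions inside another coding sequence on the same strand were left out. The footprint position was used without an offset, because the start codon peak lay at position 0. A library's leader share is the mean over up to 3316 genes of leader signal divided by leader plus ORF signal, in percent. These genes had a mean of at least 50 listed ORF positions over the 8 footprint libraries. Genes absent from a file were left out of its mean. This left 3315 or 3316 genes in footprint libraries, 3296 to 3316 in run-off files and 2889 to 3316 in monosome files. The planned summed signal could not be formed from shares. Near-cognate enrichment is the mean signal at leader triplets that differ from ATG by 1 base, divided by the mean signal at all other triplets except ATG. Single library values in groups of 2 were compared with exact permutation tests, two-sided, for which the smallest possible p is 0.33.

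For the leader ratio per gene, log2 of leader share over ORF share was taken with a pseudocount of 0.001 on both. Genes needed a mean leader share of at least 0.005 over the 8 footprint libraries, which left 2259 genes. limma 3.58.1 in R 4.3.3 was fitted over the 8 libraries with 4 groups, without an intensity trend. The pseudocount, the leader share minimum, the minimum of listed positions and the gene-wise mean were chosen after the files were seen. For mRNA, limma with an intensity trend was fitted to log2(FPKM + 1) over 12 libraries, with FPKM of at least 1 in at least 3 libraries (5616 genes). The contrasts were 37 °C against 30 °C in each strain, the difference between these shifts, and for mRNA also ded1-95 against WT at each temperature. P-values were adjusted by Benjamini-Hochberg within a contrast, and a gene was called at an adjusted p under 0.05. Other steps used python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

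The contrasts, the gene lists and the alternatives listed as planned were written before the data were examined. The 15 gene lists were Hsf1 heat shock genes, Msn2/4 stress genes, cytosolic ribosomal protein genes, ribosome biogenesis genes, initiation factor and helicase genes, glycolysis genes, genes with known AUG upstream ORFs, genes with known near-cognate extensions, mitochondrial ribosomal protein genes, proteasome genes, Gcn4 target genes, mating type genes, meiosis genes, auxotrophic marker genes and mitochondrially encoded genes. Lists with at least 5 tested genes were compared with the other genes by camera in limma, with a preset correlation of 0.01 and again with an estimated one. Camera compares changes relative to their errors, so a list can be placed higher without a larger median change. In all, 100 list tests were run. Between single or pooled files, which allow no test, each list's median was placed among 10000 random lists of as many genes with a similar mean leader level in the 8 footprint libraries. A matching on the listed positions of the shallower file, over genes with a leader position in either file, was added after the data were seen.

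Genes were named by a fixed rule. DED1 was always considered. Among genes called with the same sign in each pairing by replicate number, and for mRNA with a mean FPKM of at least 10, the 10 largest rises and the 10 largest falls were taken. Each list gave its 3 members with the smallest p. Where fewer than 5 genes passed, the 5 with the smallest p were given as values without a call. Paralogs with nearly identical sequence, such as SSA1 and SSA2, can share reads, so their values are uncertain. Between single or pooled files the 5 highest and 5 lowest ratios were taken.

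Replicate numbers were checked as pairs by correlating residuals across libraries. In mRNA, same-number correlations ran from 0.361 to 0.782 (median 0.589, 18 pairs of libraries), and different-number ones from -0.542 to -0.103 (36 pairs), so the numbers pair the libraries. The mRNA fit with the number as a block is quoted beside a result where it changes a call. No pair of mRNA libraries within a group shared identical values (0%).

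Both fits were tested on simulated data with 50 genes changed at each size and the spread of the real libraries. For mRNA without the block, 0%, 0%, 10% and 46% of changes of 1, 2, 4 and 6 on the log2 scale were recovered, and with the block 26%, 78%, 98% and 98%. For the leader ratio without the block these were 0%, 12%, 70% and 72%. False calls numbered 2, 5 and 8.

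Alternatives covered the leader window (50 nt, 200 nt and the 5' UTR marked by the authors), pseudocounts, filters, the untransformed share, the first 300 nt of the ORF in place of the whole, the median over genes, P-site offsets, quantile and coding-total scaling of FPKM, the replicate block and the omission of each library and each mRNA set. Omitting a footprint library leaves its group with 1, which the fit assumes to vary like the other groups. iCLIP signal in rRNA, tRNA, snoRNA and regions 100 nt downstream was not analysed here. DMS signal was not divided by coverage.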

Results

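Ded1p is a DEAD-box RNA helicase of budding yeast that acts in the scanning of mRNA leaders by the small ribosomal subunit. Footprints of translating ribosomes were profiled in WT and ded1-95 cells at 30 °C and after 5 min at 37 °C, with 2 replicates in each of 4 groups. Further data comprised mRNA (4 groups, 3 replicates each), footprints after run-off (1 library per group), monosome footprints (2 samples per group, pooled into 1 file), DMS probing of WT and ded1-95 at 37 °C (2 samples each, pooled) and Ded1p iCLIP at 30 °C (2 libraries that carry different protein tags). The deposited footprint values are shares of each gene's own signal, so read depth is unknown. The files list between 408356 and 1416865 positions per footprint library. The median gene had 166 and 93 listed positions in WT at 30 °C, 168 and 45 in WT at 37 °C, 181 and 66 in ded1-95 at 30 °C, and 85 and 36 in ded1-95 at 37 °C. It had 10 to 64 in run-off files, 4 to 44 in monosome files, 592 and 492 in DMS files and 121 and 3 in the iCLIP libraries. The mRNA libraries gave FPKM values, with 5329 to 5514 coding genes above 1 in replicate sets 1 and 2 and 1857 to 2336 in set 3.

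The first comparison asked how the place of ribosomes on mRNAs changed when ded1-95 cells were moved to 37 °C. Footprint signal shifted from ORFs towards leaders in most tested genes. Leader signal rose relative to ORF signal for members of each of the 13 gene lists with tested genes, among them YAP1, which encodes a transcription factor of the oxidative stress response and has known upstream ORFs, TIF6, which encodes a factor of 60S subunit maturation, and ALA1, which encodes the alanyl-tRNA synthetase and starts a longer form at a near-cognate codon. Camera, which compares changes relative to their errors, placed the 20 tested genes of cytosolic ribosomal proteins higher than other genes with a preset correlation (adjusted p = 0.00211). It did not with an estimated one (adjusted p = 0.240). The mean leader share per gene went from 2.00% ± 0.0657 (SD, n = 2) at 30 °C to 11.6% ± 0.0445 (SD, n = 2) at 37 °C, a ratio of 5.81 (exact permutation p = 0.33, two-sided, the smallest possible). The groups did not overlap, and the difference was larger than the spread between replicates.

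**Figure D1:**
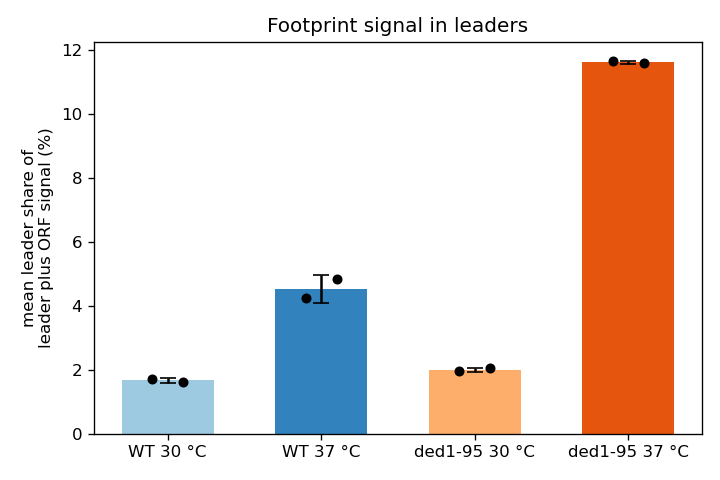
Leader share of footprint signal in percent (y axis) for the 4 footprint groups (x axis), with bars for the mean ± SD and points for the libraries (n = 2). Both ded1-95 libraries at 37 °C lie at 11.6% to 11.7%, above the other 6 libraries.

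In limma, 1723 of 2259 genes changed their leader ratio in ded1-95, and 1720 of these rose. Without adjustment 1781 genes had p under 0.05. The median change of the tested genes was 3.37 on the log2 scale, and 3.21 over the 1943 genes with a listed leader position at 30 °C. The leader share minimum was a mean over the 8 libraries, and ded1-95 at 37 °C had the highest shares. It favoured genes with leader signal in that group, so it may raise the count and the median. Of the 2259 tested genes, 316 had no leader position in either ded1-95 30 °C library. The mean leader share per library did not use this minimum. Of the called genes, 247 had no leader position listed in either 30 °C library, and no fold is given for them. APD1 (YBR151W, chromosome 2, 545028 to 545978, plus strand), which encodes a protein needed for normal actin localization, was listed at 0 at 30 °C and had leader shares of 22.6% and 37.5% at 37 °C. DCK1, which encodes a DOCK-family exchange factor, rose from 0.699% and 0% to 41.0% and 66.7%. PMT2, which encodes a protein O-mannosyltransferase, rose from 0.284% and 0% to 24.5% and 48.1%. ULP1, which encodes a SUMO protease, rose from 1.42% and 0% to 48.0% and 43.8%. RGA2, XBP1, SDH2, AVL9, KAR3 and AHC1, with roles from cell polarity to succinate dehydrogenase and microtubule motors, completed the 10 largest rises. They were listed at 0 at 30 °C, so their rank depends on the pseudocount, and reached 11.8% to 27.5%. Leader signal fell for TRZ1, which encodes the tRNA 3' processing endonuclease, from 4.44% and 1.67% to 0% in both libraries. It also fell for DPH1, a gene of diphthamide synthesis, from 1.72% and 1.56% to 0% in both. MSC1, a general stress gene, fell by 1.67 on the log2 scale (SE 0.55, adjusted p = 0.0314).

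YAP1 (YML007W, chromosome 13, 253848 to 255800, plus strand) rose by 4.44 on the log2 scale in ded1-95 (SE 0.54, limma adjusted p = 0.00221), from leader shares of 4.96% and 6.86% to 59.6% and 56.1%. In WT its change of 1.59 was not called (adjusted p = 0.0723), nor was the difference between strains of 2.86 (adjusted p = 0.178). TIF6 (YPR016C, chromosome 16, 592332 to 593069, minus strand) rose by 3.97 (SE 0.47, adjusted p = 0.00214), and ALA1 (YOR335C, chromosome 15, 946233 to 949109, minus strand) by 4.15 (SE 0.46, adjusted p = 0.00206). GRS1 (YBR121C, chromosome 2, 481364 to 483367, minus strand), which encodes the glycyl-tRNA synthetase and has a known near-cognate extension, rose by 1.67 (SE 0.42, adjusted p = 0.0124), from 3.59% and 4.39% to 11.6% and 12%. RPS12, which encodes a protein of the 40S subunit, rose from 0.514% and 0.442% to 8.11% and 7.14% (log2 change 3.84, adjusted p = 0.00213).

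The gene lists in ded1-95 were nearly uniform in direction. The leader ratio rose for 20 of 20 tested cytosolic ribosomal protein genes (20 adjusted over the list alone), led by RPL27A and RPL26B of the 60S subunit. The mRNA fit tested 135 genes of this list, so the filters left out most of its members here. It rose for 14 of 14 initiation factor and helicase genes (14 adjusted over the list alone), among them TIF3, the eIF4B gene, and CAF20, which encodes an eIF4E-binding protein. The 20 tested proteasome genes rose (20 adjusted over the list alone), with PRE1, PUP2 and RPN8 in front. Of 34 mitochondrial ribosomal protein genes 28 rose (28 adjusted over the list alone), MRPL28, MRPL4 and RSM25 first. Of 18 Hsf1 targets 16 rose (16 adjusted over the list alone), with CUR1, a gene of protein sorting under stress, SBA1, the p23 cochaperone gene, and SSA1, an Hsp70 gene whose paralog SSA2 shares reads. Of 17 Gcn4 targets 15 rose (15 adjusted over the list alone), led by LYS9, TRP4 and LEU4 of amino acid synthesis. Of 18 Msn2/4 stress genes 10 rose and MSC1 fell (11 adjusted over the list alone), with DDR2 and TSL1 beside XBP1. Of 16 ribosome biogenesis genes 10 rose (10 adjusted over the list alone), among them UTP22 of the small subunit processome, from 1.61% and 0.48% to 21.5% and 21.1%, and NOG2, a GTPase gene of 60S maturation. Of 5 glycolysis genes 4 rose (4 adjusted over the list alone), HXK2, TDH2 and PFK1 first, and of 6 genes with known AUG upstream ORFs 4 rose (4 adjusted over the list alone), with SCH9, a growth-control kinase gene, and FOL1, a folate synthesis gene, beside YAP1. Both tested genes with known near-cognate extensions rose (2 adjusted over the list alone), as did 3 of 4 mating type genes (3 adjusted over the list alone), MFA2, BAR1 and AGA2, and 3 of 3 auxotrophic marker genes (3 adjusted over the list alone), LYS2, ADE2 and CAN1. No meiosis gene and no mitochondrially encoded gene passed the filter, and DED1 itself was not tested.

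Against the other genes, camera placed the ribosomal protein genes higher in ded1-95 (median 3.66, adjusted p = 0.00211, 20 of 20 genes up), and adjusted p = 0.240 with an estimated correlation. It placed the Msn2/4 genes lower (median 2.44, or 1.98 over the 14 with leader signal at 30 °C, adjusted p = 0.0204), and adjusted p = 0.240 with an estimated correlation. For the Hsf1 genes the median of 2.21 lay below that of all tested genes while the test pointed up without a call (adjusted p = 0.853).

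In WT cells the leader share of footprint signal was also higher at 37 °C, by less than in ded1-95. The leader share went from 1.67% ± 0.0737 (SD, n = 2) to 4.54% ± 0.438 (SD, n = 2), a ratio of 2.72 (exact permutation p = 0.33, two-sided). TIF6, ALA1 and the ribosomal stalk genes RPP0 and RPP2B were among the genes that rose. DBP3, which encodes a DEAD-box helicase of ribosome biogenesis, was the only called gene that fell in WT. In limma 570 genes changed, of which 569 rose, and 1054 had p under 0.05 without adjustment. The median change was 1.78, and 1.71 over the 1948 genes with a listed leader position at 30 °C. For 113 of the 570 no leader position was listed at 30 °C. With a 50 nt leader window 261 genes were called, and with the untransformed leader share 102, of which 76 were shared. A fit with the replicate number as a block called 350, of which 339 were shared. With 1 library left out its group keeps 1 library, which is then assumed to vary like the other groups. In such fits the WT count was 20 without WT 30 °C replicate 2, 25 without WT 37 °C replicate 2, 149 without WT 37 °C replicate 1, and 300 without either ded1-95 37 °C replicate.

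The 10 largest rises in WT on the log2 scale were LEU3 (5.88% and 26.3% at 37 °C), HOF1, MPC3, MRPL16, CBP6, MSA1, PFK26, MSN1, GZF3 and MCX1. Each was listed at 0 at 30 °C, so its rank depends on the pseudocount. These genes act in transcription control (LEU3, MSN1, GZF3, MSA1), cytokinesis (HOF1), mitochondria (MPC3, MRPL16, CBP6, MCX1) and glycolytic control (PFK26). TIF6 rose by 2.47 (adjusted p = 0.0274), from leader shares of 6.04% and 4.99% to 20.2% and 29.7%. RPP2B rose by 2.24 (adjusted p = 0.0319), from 4.73% and 3.95% to 17.7% and 18.0%. ALA1 rose by 2.02 (adjusted p = 0.0357), whereas the change of GRS1 was not called (1.07, adjusted p = 0.0967). DBP3 (YGL078C, chromosome 7, 360288 to 361859, minus strand) fell from 0.632% and 0.913% to 0% in both WT libraries.

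By list, 12 of 20 ribosomal protein genes rose in WT (17 adjusted over the list alone), with RPP0, RPL26B and RPP2B first. Among initiation factor and helicase genes 7 of 14 rose (11 adjusted over the list alone), including TIF3 and SUI2, the eIF2 alpha gene. Of proteasome genes 7 of 20 rose (11 adjusted over the list alone), with PRE5 and RPN8, and of mitochondrial ribosomal protein genes 10 of 34 (13 adjusted over the list alone). Of Hsf1 targets 6 of 18 rose (8 adjusted over the list alone), among them CUR1, SSA1 and the Hsp90 gene HSP82. Of Msn2/4 genes 3 of 18 rose (6 adjusted over the list alone), which were SPI1, XBP1 and PNC1, and of Gcn4 targets 5 of 17 (6 adjusted over the list alone), with ARO4 and TRP2. DBP3 was the only called biogenesis gene of 16 (1 adjusted over the list alone). No gene was called by limma among 5 glycolysis genes (3 adjusted over the list alone), 6 genes with AUG upstream ORFs (0 adjusted over the list alone) and 4 mating type genes (0 adjusted over the list alone). ALA1 was called of the near-cognate genes (2 adjusted over the list alone), and CAN1 of the markers (3 adjusted over the list alone). Camera placed the biogenesis genes lower than other genes (median 1.06, adjusted p = 0.0010), and adjusted p = 0.279 with an estimated correlation. It placed the ribosomal protein genes higher (adjusted p = 0.0273, and adjusted p = 0.279 with an estimated correlation), although their median of 1.77 lay just under the 1.78 of all tested genes.

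Whether the strains differed in this response was tested as the difference of the shifts. Signal shifted further towards leaders in ded1-95 than in WT. The leader share rose by 7.19 percentage points more in ded1-95 in replicate 1 and by 6.31 in replicate 2 (mean 6.75). The strains were closer at 30 °C, where the leader share of ded1-95 was 1.20 times that of WT, than at 37 °C, where it was 2.56 times (exact permutation p = 0.33 for each, two-sided). Both comparisons exceeded the spread between replicates. The depth behind the shares is unknown, and the libraries of ded1-95 at 37 °C list the fewest positions within each replicate. Among 281 genes with a mean of at least 500 listed ORF positions, where shares were lower, the mean difference was 3.60 points. Their share rose 6.18 times in ded1-95 and 2.53 times in WT, against 5.81 and 2.72 times over all genes.

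Gene by gene, 10 genes passed in limma, each with a larger rise in ded1-95, and 510 had p under 0.05 without adjustment. They were RGA2, a gene of cell polarity, DBP3, and DAT1, CST26, IOC3, SAS4, SPC29, ARP6, RCF2 and ZIM17, with roles from chromatin to mitochondria. A 50 nt leader window and a fit with the replicate number as a block each called 0 genes. The untransformed leader share called 732, of which 4 were among these 10. Of these 10, 8 had leader positions listed only in the 2 libraries of ded1-95 at 37 °C, such as DAT1 (8.33% and 12.5%) and CST26 (4.84% and 10.5%). These 8 passed the leader share minimum only through that group, the one found higher. In the other 6 libraries their leader value rests on the pseudocount. Their calls are therefore no separate support for a strain difference. RGA2 (YDR379W, chromosome 4, 1230167 to 1233196, plus strand) had 2.30% and 0.943% in WT at 30 °C, 1.49% and 1.85% in WT at 37 °C, 0% in both ded1-95 libraries at 30 °C, and 17.1% and 23.5% in ded1-95 at 37 °C (adjusted p = 0.0382). DBP3 went from 0.93% and 1.18% to 8.57% and 8.11% in ded1-95, against its fall in WT (adjusted p = 0.0382). With 1 library left out, and the lone library of its group assumed to vary like the others, no gene passed without WT 30 °C replicate 1 or 2, ded1-95 30 °C replicate 1 or 2, WT 37 °C replicate 2, or ded1-95 37 °C replicate 2 (0 in each case), whereas 56 passed without WT 37 °C replicate 1 and 40 without ded1-95 37 °C replicate 1.

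The 20 tested cytosolic ribosomal protein genes were placed higher by camera in the difference of the shifts (median 1.87, adjusted p = 0.00579), against a median of 1.51 for all tested genes. They are the part of the list that passed the filters, which include a minimum of leader signal. The call did not hold with an estimated correlation (adjusted p = 0.388). Adjusted over the list alone, BAR1, a protease gene of the pheromone response, and MFA2, an a-factor gene, made 2 of 4 mating type genes. The counts adjusted over the list alone were 2 of 18 Msn2/4 genes, 2 of 16 biogenesis genes and 1 of 2 near-cognate genes. They were 0 for the Hsf1, ribosomal protein, initiation, glycolysis, upstream ORF, mitochondrial ribosomal protein, proteasome, Gcn4 and marker lists. TIF4632, which encodes eIF4G2, was not called (2.93, adjusted p = 0.18).

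Within ORFs, the share of signal in the first 300 nt was 44.9% ± 1.25 in WT at 30 °C, 50.5% ± 1.66 in WT at 37 °C, 44.8% ± 0.295 in ded1-95 at 30 °C and 60.7% ± 3.50 in ded1-95 at 37 °C (SD, n = 2 each). The start codon held 4.69% ± 1.23, 4.53% ± 0.534, 4.74% ± 0.402 and 6.40% ± 0.459 of ORF signal in the same order (SD, n = 2 each).

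Where in the leaders the ribosomes stood was asked through the codon at the footprint position. Mean signal was higher at near-cognate codons, which differ from ATG by 1 base, than at other triplets in each group. Not every near-cognate triplet was enriched, and triplets of TG and any base, outside this class, were enriched too. The enrichment of the class was lower at 37 °C than at 30 °C in both strains, while the signal at near-cognate codons was higher. Near-cognate enrichment over other triplets was 2.48 ± 0.379 in WT at 30 °C, 1.85 ± 0.410 in WT at 37 °C, 2.24 ± 0.448 in ded1-95 at 30 °C and 1.63 ± 0.0662 in ded1-95 at 37 °C (SD, n = 2 each; exact permutation p = 0.33 for either strain, two-sided). In ded1-95 the mean signal at near-cognate triplets was 4.21 times higher at 37 °C and that at other triplets 5.75 times, against 2.22 and 2.95 times in WT. The change of enrichment differed between strains by 0.320 in replicate 1 and -0.265 in replicate 2, so no difference held up. The mean was 0.0273, and it was -0.263 without WT 37 °C replicate 1, -0.290 without ded1-95 30 °C replicate 1, -0.240 without WT 30 °C replicate 2 and -0.0196 without ded1-95 37 °C replicate 2.

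**Figure D2:**
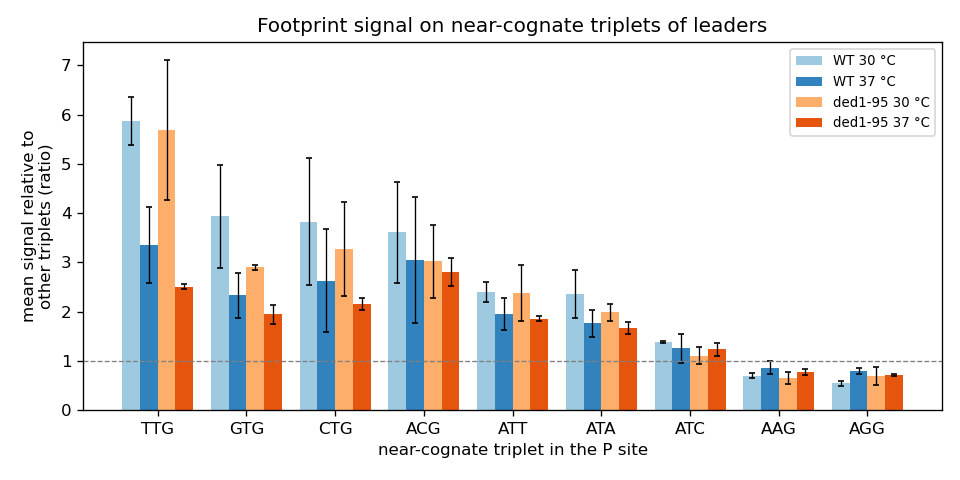
Mean footprint signal at each of 9 near-cognate leader triplets relative to other triplets (y axis, ratio) in the 4 footprint groups, with a dashed line at 1. TTG stood highest in WT at 30 °C at 5.88, and AAG and AGG lay below 1 there.

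Of the near-cognate triplets TTG had an enrichment of 5.88 in WT at 30 °C, 3.35 in WT at 37 °C, 5.69 in ded1-95 at 30 °C and 2.51 in ded1-95 at 37 °C. In the same order GTG had 3.93, 2.33, 2.90 and 1.94, CTG 3.83, 2.63, 3.27 and 2.16, and ACG 3.61, 3.04, 3.02 and 2.80. AAG (0.70, 0.86, 0.65 and 0.77) and AGG (0.54, 0.80, 0.69 and 0.71) were not enriched. ATG itself occurred at 269 leader positions. Its enrichment was 32.7 ± 7.30, 11.5 ± 2.95, 28.6 ± 9.48 and 8.90 ± 0.416 in that order (SD, n = 2 each). The mean signal at ATG did not fall, and at 37 °C it was 1.80 times that at 30 °C in ded1-95 and 1.05 times in WT. The in-frame share of ORF signal also differed between libraries. It was 57.85% and 58.9% in WT at 30 °C, 44.64% and 58.03% in WT at 37 °C, 48.75% and 56.51% in ded1-95 at 30 °C, and 46.04% and 49.31% in ded1-95 at 37 °C.

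The mRNA libraries asked which transcripts changed over the same 5 min. Heat shock and stress transcripts stood higher at 37 °C in both strains, and ribosomal protein and ribosome biogenesis transcripts lower, but not in each replicate set. These list calls rest on a preset correlation between genes, and none held with an estimated one (adjusted p by camera from 0.395 to 0.998). Unless the block is named, list p-values come from the fit without it, which leaves out the pairing of the sets. With the block, too, 0 list calls held with an estimated correlation. No single gene was called. In set 1 the heat genes did not move with temperature, whereas they did in sets 2 and 3. DED1 (YOR204W) changed by -0.19 in ded1-95 and -0.17 in WT and was 0.30 higher in ded1-95 at 30 °C and 0.28 at 37 °C, without a call.

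**Figure D3:**
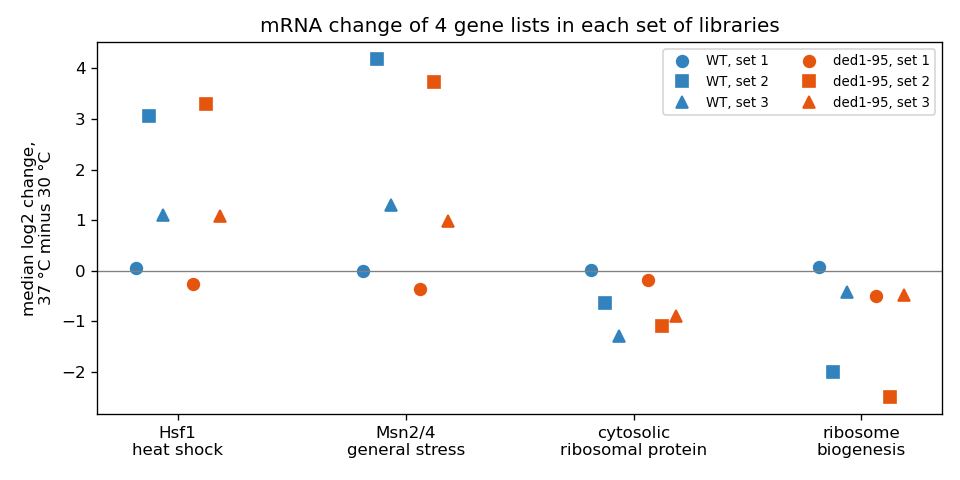
Median log2 change of FPKM from 30 °C to 37 °C (y axis) of 4 gene lists (x axis), with a symbol for each replicate set and a colour for each strain. Changes are not relative to all genes. The Hsf1 list lies at 0.06 and -0.26 in set 1, at 3.05 and 3.30 in set 2 and at 1.09 and 1.08 in set 3 (WT and ded1-95).

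In limma 0 genes passed in each of the 5 contrasts. At an unadjusted p under 0.05 there were 16 genes for ded1-95, 23 for WT, 22 for the difference of the shifts, 26 for ded1-95 against WT at 30 °C and 22 at 37 °C. The fit with the replicate number as a block also gave 0. The smallest p-values belonged to short ORFs listed at 0 in several libraries, for which no fold is given. In ded1-95 these were YFR012W-A (limma adjusted p = 0.346), YGR146C-A, MIN4, YMR254C and YBL071C-B, and in WT YMR272W-B (adjusted p = 0.921), YDR169C-A, YBR144C, YMR242W-A and BRP1. YMR272W-B, YBL071C-B, YDR169C-A, YOR105W and LSO1 led the difference of the shifts. DGR1, YBR196C-A, YDR246W-A, YOL131W and YLR296W led the strain comparison at 30 °C, and YBL071C-B, YML054C-A, YMR272W-B, YBR144C and MIN6 that at 37 °C. With 1 library left out, the counts were 2 for ded1-95 without ded1-95 30 °C replicate 3 and 1 without WT 30 °C replicate 2. For WT the count was 1 without ded1-95 30 °C replicate 1 or WT 37 °C replicate 3. For the difference it was 1 without WT 30 °C replicate 2, WT 37 °C replicate 3 or ded1-95 30 °C replicate 3. At 30 °C it was 1 without ded1-95 30 °C replicate 3. At 37 °C it was 2 without WT 37 °C replicate 3, and 1 without ded1-95 30 °C replicate 1 or ded1-95 37 °C replicate 3.

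The median of all genes changed by -0.26 in ded1-95 in the deposited scale, and by -0.04 and -0.07 after quantile scaling and scaling to the coding total. In WT it changed by 0.01, -0.03 and 0.18. Leaving out 1 library unbalances the paired sets, and this median then ranged from -1.18 to 0.69 in ded1-95 and from -0.90 to 0.97 in WT. Without set 1, 2 or 3 as a whole it was -0.18, -0.29 and -0.26 in ded1-95 and -0.03, -0.02 and 0.05 in WT. Relative to this median, the Hsf1 genes (30 tested) stood 1.54 higher in ded1-95 (adjusted p = 1.9e-21) and 1.42 higher in WT (adjusted p = 6.8e-16), with the sign kept under each scaling. Neither call held with an estimated correlation (adjusted p = 0.423 and 0.692). HSP26, a small heat shock protein gene, had log2 changes by set of -0.05, 6.55 and 3.64 in ded1-95 and 0.07, 6.27 and 3.51 in WT. HSP30, SSA4 and BTN2, genes of membrane stress, Hsp70 and protein aggregation, were the other leading members. In set 1, 4 of 30 Hsf1 genes were higher at 37 °C in ded1-95 and 20 in WT, against 30 and 29 in set 2 and 25 and 28 in set 3. These counts are not relative to all genes, whose median in set 1 changed by -0.33 in ded1-95 and 0.05 in WT. The Hsf1 median in ded1-95 set 1 was -0.26, slightly above that of all genes. Without set 1 the median changes were 2.02 in ded1-95 and 2.11 in WT.

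The Msn2/4 genes (30 tested) stood 1.76 higher than all genes in ded1-95 (adjusted p = 1.9e-27) and 1.83 higher in WT (adjusted p = 6.2e-31), led by SPI1, HSP30 and PGM2 and by DDR2, HSP12 and SOL4. Neither call held with an estimated correlation (adjusted p = 0.423 and 0.395). By set their medians were -0.37, 3.73 and 0.99 in ded1-95 and 0.00, 4.18 and 1.29 in WT, and without set 1 they were 2.42 and 2.71. Medians by set and without set 1 are given here as they are, not relative to all genes. All genes had medians by set of -0.33, -0.15 and -0.12 in ded1-95 and 0.05, 0.04 and -0.05 in WT. Ribosomal protein genes (135 tested) stood lower by -0.50 in ded1-95 (camera adjusted p = 2.2e-05) and -0.64 in WT (adjusted p = 4.6e-10). Their medians by set were -0.18, -1.10 and -0.89 in ded1-95 and 0.02, -0.64 and -1.29 in WT. In ded1-95 set 1 their median of -0.18 thus lay above the -0.33 of all genes. With an estimated correlation neither was called (adjusted p = 0.998 and 0.854). Without set 1 their medians were -1.03 and -0.98. Biogenesis genes (40 tested), such as NOP1 and NOG1 in ded1-95 and BRX1 in WT, stood lower by -0.96 (adjusted p = 3.6e-12) and -0.86 (adjusted p = 3.4e-12), and were not called with an estimated correlation (adjusted p = 0.720 and 0.854). By set they had medians of -0.50, -2.50 and -0.48 in ded1-95 and 0.08, -2.0 and -0.42 in WT, and without set 1 of -1.51 and -1.25. Initiation factor and helicase genes (33 tested), such as GCD1 of eIF2B and PAB1, the poly(A)-binding protein gene, stood lower by -0.35 (adjusted p = 0.0299) and -0.42 (adjusted p = 0.0121), with a median of -0.69 in either strain without set 1. These calls were lost with an estimated correlation (adjusted p = 0.998 and 0.854).

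Glycolysis genes (18 tested), led by HXK1 and GLK1, were placed higher in ded1-95 (adjusted p = 0.0133, and 0.998 with an estimated correlation). Their median was -0.02 in the deposited scale while their mean was 0.31, and relative to all genes the median was 0.24. Auxotrophic markers (5 tested) were placed lower in ded1-95 (median -0.43, adjusted p = 0.00863, 0.570 with an estimated correlation and 0.380 with the replicate block). Relative to all genes they stood at -0.17, but at 0.08 after scaling to the coding total. HIS3, a gene of histidine synthesis and a marker, was listed at 195 FPKM in 1 of the ded1-95 30 °C libraries and at 0 in the other 2.

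The other lists were not called for mRNA in either strain: AUG upstream ORF genes (15 tested), mitochondrial ribosomal protein genes (67), proteasome genes (32), Gcn4 targets (30), mating type genes (8), meiosis genes (10) and mitochondrially encoded genes (8). The 3 near-cognate genes were too few to test. The median of the mitochondrial ribosomal protein genes in ded1-95 was -0.20 while the test pointed up. With the replicate block the Gcn4 targets were placed lower in ded1-95 (adjusted p = 0.0207, and 0.361 with an estimated correlation) and the mitochondrially encoded genes higher (adjusted p = 0.0170, and 0.412). By limma no list gene passed over all genes in either strain. Adjusted over the list alone, 1 marker gene, HIS3, passed in ded1-95, and 0 in the other lists. With the block 6 initiation genes and 1 Gcn4 gene passed over the list alone, and the marker gene did not.

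Between strains, no list was called for mRNA in the difference of the shifts (smallest adjusted p = 0.34), at 30 °C (0.219) or at 37 °C (0.0778, mitochondrially encoded genes). With the replicate block the mitochondrially encoded genes, which include COX3 of cytochrome oxidase and ATP8 of the ATP synthase, were placed higher in the difference (median 0.36, adjusted p = 7.8e-04, and 0.953 with an estimated correlation) and at 37 °C (median 0.27, adjusted p = 2.2e-05, and 0.569). With the block at 30 °C the ribosomal protein genes (median -0.17, adjusted p = 0.00127, and 0.958) and mating type genes (median -0.50, adjusted p = 0.00262, and 0.958) were placed lower. Adjusted over the list alone, 0 genes of any list passed in these 3 comparisons by limma, with or without the block.

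Run-off, monosome and DMS data had 1 file per group, so no test was possible. After run-off the leader share was 1.64% in WT at 30 °C, 1.40% in WT at 37 °C, 1.68% in ded1-95 at 30 °C and 1.73% in ded1-95 at 37 °C. Relative to the first 300 nt of the ORF alone it was 6.83%, 5.47%, 7.55% and 8.24%. On that measure the ordinary footprint libraries stood at 4.39% and 4.20% in WT at 30 °C, 8.85% and 9.57% in WT at 37 °C, 4.90% and 5.11% in ded1-95 at 30 °C, and 16.5% and 17.5% in ded1-95 at 37 °C. On that measure run-off values were thus higher than footprint values at 30 °C and lower at 37 °C in both strains. Over the whole ORF, footprint values at 30 °C were 1.72% and 1.62% in WT and 1.95% and 2.05% in ded1-95. There run-off lay between the WT values and below those of ded1-95, and it was lower at 37 °C in both strains. In monosomes the leader share over the whole ORF was 2.82% and 5.67% in WT at 30 °C and 37 °C, and 3.65% and 7.57% in ded1-95. Relative to the first 300 nt it was 6.89%, 12.6%, 8.58% and 13.5%. In points, the rise in monosomes was larger in ded1-95 than in WT by 1.06 over the whole ORF, but the difference was -0.754 against the first 300 nt. As a fold over the whole ORF the rise was similar in both strains, from a higher start in ded1-95. The ded1-95 mean at 37 °C covered 2889 genes, against 3316 in the other monosome files. Among 47 genes with enough listed positions in ded1-95 monosomes, ATG41, an autophagy gene, stood highest at 37 °C relative to 30 °C (26.5% against 1.48%), followed by RPS4B (4.17% against 0.178%), HOR7, YDR524C-B and RPL27A. RPL35B, HSP104, HTA2, RPL26B and HYP2 stood lowest. Among 433 genes in WT monosomes VPS1, SAM2, TSC13, NIP1 and YMR315W stood highest and ERG9, TOM20, HEM2, ERG6 and RPB10 lowest. Among 747 genes in ded1-95 run-off ENA1, a sodium pump gene (11.3% at 37 °C, listed at 0 at 30 °C), PSK1, VOA1, GRX7 and BTN2 stood highest and NFS1, CDC34, VPS17, SWI5 and NUS1 lowest. Among 258 genes in WT run-off PYC2, PSE1, NUP159, SRP1 and GLC7 stood highest and CIT2, PDI1, RPS15 (0.0787% against 2.68%), ALD5 and YDR524C-B lowest. Many genes have no leader position in these files, so each list's median was also placed among random lists matched on listed positions, over genes with a leader position in either file. The ribosomal protein list then lay at percentile 97.69 in ded1-95 monosomes (median log2 ratio 2.48), 85.05 in WT monosomes (1.48), 100 in ded1-95 run-off (1.70) and 19.27 in WT run-off (-0.78). Matched on leader level alone, the percentiles were 99.95, 94.62, 100 and 0.00.

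DMS marks unpaired adenines and cytosines, and iCLIP marks sites where Ded1p touches RNA. At 37 °C the leader share of DMS signal was 1.17% in ded1-95 and 1.46% in WT. Among 2256 genes CSM1, a gene of meiotic chromosome segregation (0% in ded1-95 against 3.95% in WT), MRPL25, YKL068W-A, SLF1 and CYT2 stood lowest. ENA1 (2.59% against 0%), CMI8, UME1, BET1 and VPH2 (2.22% against 0.0492%) stood highest. DED1 had 0.00638% in ded1-95 and 0.00215% in WT. For Ded1p iCLIP, shares were averaged over 4264 and 3553 genes in the 2 libraries, with equal weight per gene. These means were 9.70% and 12.4% in 5' UTRs, 76.1% and 82.9% in ORFs and 13.9% and 4.54% in 3' UTRs. In the first library 34292 positions without a gene were left out. Across 3173 genes the 5' UTR shares of the 2 libraries had Pearson's r = 0.359 and a Spearman rank correlation of 0.408, where genes are not independent replicates.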

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

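Of the tests in this part, the contrasts and list tests were planned, and the explanations weighed against them were all tested after the result was seen.

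A difference between the strains singled out 10 genes whose leader ratio rose more in ded1-95 than in WT. It also singled out the 20 tested cytosolic ribosomal protein genes as a list (camera adjusted p = 0.00579, and 0.388 with an estimated correlation). Both come from tests of the difference itself, and with the replicate number as a block 0 genes passed. Of the 10 genes, 8 had leader positions only in the ded1-95 37 °C libraries and passed the leader share minimum only through them. Leaving out 1 library leaves its group with 1, which is assumed to vary like the other groups. In such fits 0 genes passed without WT 30 °C replicate 1 or 2, ded1-95 30 °C replicate 1 or 2, WT 37 °C replicate 2 or ded1-95 37 °C replicate 2, 56 passed without WT 37 °C replicate 1, and 40 without ded1-95 37 °C replicate 1.

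The leader share rose more at 37 °C in ded1-95 than in WT, by 6.75 percentage points on average. A few genes with most of the leader signal are argued against, since the median gene also rose further in ded1-95, by 3.41 and 3.37 points by replicate (mean 3.39). A loss of ribosomes beyond the first 300 nt of the ORF could explain a part but not the whole: relative to the first 300 nt the share rose 3.39 times in ded1-95 and 2.14 times in WT (mean ratio 1.58, SD 0.117, n = 2), against 5.81 and 2.72 times over the whole ORF. Fewer listed positions in the ded1-95 37 °C libraries are argued against as the whole cause. Within the 4 groups one library lists 1.62 to 2.82 times as many positions as the other. Yet the share in the library with fewer was higher by at most 0.620 points (SD of the 4 differences 0.33). Among genes with at least 500 listed positions, where shares were lower, the difference was 3.60 points. There the share rose 6.18 times in ded1-95 and 2.53 times in WT. The mean ratio of these folds was 2.50 (SD 0.719, n = 2), against 2.16 (SD 0.381, n = 2) over all genes. Shares carry no level, so more leader ribosomes and fewer ORF ribosomes could each give the pattern, and the strain as its cause is possible and untested.

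In mRNA set 1 the heat genes did not move with temperature. Swapped 30 °C and 37 °C labels would lower the Hsf1 median at the labelled 37 °C in set 1 by about as much as it rose in sets 2 and 3. The lower strain median was -0.26, in ded1-95, against rises of 1.08 to 3.30. The median of all genes there was -0.33, so the Hsf1 list did not fall relative to all genes. Set 1 cultures that were already stressed at 30 °C are consistent with the Hsf1 list there, which stood 2.09 higher relative to all genes than in the higher of the other sets. The groups give no biological explanation for a set, and none was tested.

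Near-cognate enrichment was lower at 37 °C in both strains. Blurred footprint positions could lower it, and in each of the 4 groups the library with the lower in-frame share also had the lower enrichment. That library was replicate 1 in each group, which also listed more positions, so the 4 groups are not independent here. A fit with the in-frame share beside the groups did not include the replicate number. In it the mean change at 37 °C went from -0.624 to -0.301 (95% interval -0.934 to 0.33, 3 residual degrees of freedom). With so few libraries blurring and an effect of temperature cannot be told apart.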

How the results depend on the processing

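Chosen after the data were seen were the smaller pseudocount, the higher leader minimum, the untransformed share, the authors' 5' UTR, the minimums of 20, 100 and 500 positions, coding-total scaling, omission of mRNA sets, the first 300 nt of the ORF, the median gene in single files, random lists matched on listed positions, and near-cognate enrichment without the top 1% of genes. The block and the omission of set 1 in list tests were also added later. The other alternatives were planned. Footprints in ORFs (5 results) and translational efficiency (3 results) were not run with any alternative.

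Where 1 footprint library is left out, the other library of its group is assumed to vary like the other groups. In the leader ratio same-number libraries correlated by 0.013 to 0.105. With 2 libraries per group the different-number correlations mirror these values, so this check cannot show that the libraries are unpaired. In each group replicate 2 listed fewer positions and had a higher in-frame share than replicate 1. The count for ded1-95 of 1723 genes stayed within 1.5 times under each alternative run, with 1336 to 1753 when 1 library was left out. The WT count of 570 moved to 261 with a 50 nt window, 290 with the smaller pseudocount, 350 with the replicate block (339 shared), 102 with the untransformed share (76 shared) and 372 with a minimum of 20 positions. With 1 library left out it was 20 (without WT 30 °C replicate 2) to 424, with 25 without WT 37 °C replicate 2, 149 without WT 37 °C replicate 1 and 300 without either ded1-95 37 °C replicate. The 10 genes of the strain difference became 0 with a 50 nt window, 22 with 200 nt, 39 with the smaller pseudocount, 2 with the higher leader minimum, 0 with the block, 732 with the untransformed share (4 shared) and 4 with the authors' 5' UTR. Leaving out 1 library gave 0 to 56. It gave 0 without either 30 °C replicate of either strain, WT 37 °C replicate 2 or ded1-95 37 °C replicate 2, 40 without ded1-95 37 °C replicate 1, and 56 without WT 37 °C replicate 1. The cause was not tested.

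The strain difference in leader share of 6.75 points was 4.45 with 50 nt, 7.94 with 200 nt, 9.27 with the authors' 5' UTR, 3.39 for the median gene, 6.22 with at least 100 positions, 3.60 with at least 500, 7.04 against the first 300 nt, and 6.44 to 7.06 with 1 library left out. The sign held in each, and the cause was not tested. The near-cognate difference of 0.0273 ranged from -0.290 (without ded1-95 30 °C replicate 1) to 0.344 and also reversed to -0.263 without WT 37 °C replicate 1, -0.240 without WT 30 °C replicate 2 and -0.0196 without ded1-95 37 °C replicate 2. Other alternatives gave 0.0056 to 0.118.

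The 0 genes of the mRNA contrasts stayed 0 with other scalings, filters, the block and without any set. The exception was a pseudocount of 0.1, with 1 gene for ded1-95 against WT at 37 °C, of which the cause was not tested. Leaving out 1 library gave 0 to 2 for ded1-95 and at 37 °C (2 without ded1-95 30 °C replicate 3 and without WT 37 °C replicate 3), and 0 to 1 for WT, the difference and 30 °C. The other libraries whose omission called 1 gene were WT 30 °C replicate 2 for ded1-95 and the difference, ded1-95 30 °C replicate 1 for WT and at 37 °C, WT 37 °C replicate 3 for WT and the difference, ded1-95 30 °C replicate 3 for the difference and at 30 °C, and ded1-95 37 °C replicate 3 at 37 °C. The median residual SD was 1.74 on the log2 scale, and 0.403 with the block.

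Of 100 list tests 17 were called, 0 with an estimated correlation, 23 with the block and 18 without set 1. For the leader ratio the block added the initiation genes in ded1-95 (adjusted p = 0.0396, and 0.313 with an estimated correlation) and changed no other list call. Between single files, the monosome difference of 1.06 was 0.943 with 50 nt and 0.613 with 200 nt, and reversed to -0.754 against the first 300 nt, of which the cause was not tested. Its -0.694 for the median gene decides nothing, since 886 of 2889 genes have a leader position in the ded1-95 37 °C file and its median is 0. In the same order the run-off difference of 0.292 was 0.185, 0.491, 2.05 and 0, the DMS difference of -0.292 was -0.237, -0.330, -0.983 and -0.233, and the iCLIP mean of 9.34% was 6.44%, 10.6%, 20.3% and 2.5%. The cause was not tested. The median gene has 0 in all 4 run-off files and in the second iCLIP library, so the 0 and the 2.5% decide nothing either. Without read totals, depth limits each share to an unknown degree.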

Other observations

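The counts from other splits of the mRNA samples were computed after the result was seen, and so was the matching of random lists on listed positions. The list percentiles matched on leader level were planned.

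For each mRNA comparison the 6 samples allow 10 splits, too few for a share under 0.05. The real count was 0 and the highest other count was 80 for ded1-95, 23 for WT, 44 for the strains at 30 °C and 726 at 37 °C. Such counts point to a structure of the samples, the replicate sets. Among the 4 splits that part all 3 numbers, as the real one does, the highest other count was 0.

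The TGN triplets, which begin 1 nt downstream of an NTG triplet, also stood high in WT at 30 °C, with enrichments of 3.50 for TGA, 3.42 for TGT, 2.92 for TGG and 2.59 for TGC.

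In monosomes the Msn2/4 list lay at percentile 99.87 of random lists matched on leader level in ded1-95 (99.39 matched on listed positions) and 97.82 in WT (96.76), and the proteasome list at 99.71 in ded1-95 (95.05). After run-off the biogenesis and proteasome lists lay at 0.40 (18.40) and 0.71 (0.47) in ded1-95, the Hsf1 list at 0.03 (4.66) and the Gcn4 list at 99.31 (93.81) in WT. In DMS the Msn2/4 list lay at 1.09 (0.92) and the mitochondrial ribosomal protein list at 4.06 (41.18). The monosome file of ded1-95 at 37 °C has a median of 4 listed positions per gene.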
